A study of Mus musculus with 12 samples.

How the data were processed

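RNA from calvariae, the flat bones of the skull vault, of mouse embryos at embryonic day 17.5 (C57BL/6) was sequenced in 12 libraries. The labels give 2 genotypes, wild type (WT) and heterozygous for Runx2 (Runx2+/-). They give 2 treatments, vehicle or MS-275 (entinostat, an inhibitor of class I histone deacetylases), with 3 replicates in each of the 4 groups. Per the labels' protocols, parents were mated at 8 weeks of age, and pregnant dams were injected intraperitoneally 2 times, on day 14.5 and again on day 16.5 post coitum, with 10 mg of MS-275 per kg. The labels do not say whether the replicates of a group came from separate animals or litters, so the p-values measure the spread among these samples. Xist and Y-linked counts, read outside the rule for named genes, were 72182 and 80 in Runx2+/- vehicle replicate 3, which leaves open whether it came from 1 embryo. All 3 Runx2+/- MS-275 libraries were high in Xist (29300 to 79127 counts), while each other group held libraries with 19585 or more and with 60 or fewer, so sex is not balanced between the groups. Nor do they say which part of Runx2 is deleted.

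The deposited values are read counts per Ensembl gene, as whole numbers without normalization, in 1 file per library. The authors' steps, per the submitters' processing notes, used Trimmomatic, Bowtie2, SAMtools and HTSeq, with versions not given in the sources used here. Those notes give the build as GRCh38.p7, a human build, while the gene identifiers in the files are mouse Ensembl identifiers. The files hold no coordinates, so positions printed here come from GENCODE M21 (GRCm38) by gene identifier. The library kit marks strand and starts from total RNA, per the labels' protocols, but the strand setting of the counting is not given in the sources used here. Counts of antisense or overlapping genes are therefore uncertain. The same holds for near-identical copies whose reads the counting could split, such as Bglap and Bglap2, the Lce1 genes, the globins and the histone genes. Each file ends with 5 summary entries that name no gene, and these stayed out of library sizes and tests. Reads assigned to no gene made up 5.21% to 22.2% of uniquely aligned reads in a library, ambiguous reads 3.25% to 4.78%, and reads with more than 1 alignment 14.0% to 20.1% of all reads in the file. Of the gene identifiers, 37607 had a symbol in the reference table, and 1572 had none and held 0.217% of the counts.

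The total count in genes was 13307456 to 19399760 per library, and 20008 to 24666 genes had at least 1 count. A gene with no count could still have had up to 3 counts, a floor of 0.120 to 0.279 CPM in a library on the TMM scale given below, and fold bounds use its mean over the libraries of a group (0.233 CPM in WT MS-275). This floor, and every interval that rests on counts, covers counting error only, since reads without molecular identifiers are not independent molecules.

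Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3 were used. Genes were kept by filterByExpr on the 4 groups, which left 17967 genes. Counts were scaled by the trimmed mean of M values (TMM), with factors of 0.598 to 1.33, and CPM values below are scaled this way and given as mean ± SD over 3 libraries. All 12 libraries entered 1 fit with 4 group means and no covariate, by the quasi-likelihood F test of edgeR 4.0.16 with robust estimation and 8 residual degrees of freedom. The common biological coefficient of variation was 0.442. Comparisons were the 2 drug differences, the 2 genotype differences, Runx2+/- MS-275 against WT vehicle, and the interaction (the drug difference in Runx2+/- minus that in WT). Within each comparison p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Every adjusted p of a gene is from this test unless another is named, and it is two-sided. The standard error (SE) of a log2 fold change is its size divided by the square root of F. With 3 libraries against 3, an exact permutation test cannot give a p below 0.1, so none is printed for a single gene.

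Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the 25 lists within a comparison. They cover osteoblast differentiation and bone matrix, mineralization and early osteocyte, osteoclast, chondrocyte, suture mesenchyme and osteoprogenitor, the WNT, BMP and TGF-beta, and FGF and hedgehog pathways, and the HDAC family. Others cover HDAC-inhibitor response, proliferation, apoptosis and p53 response, skeletal muscle, epidermis, neuron, glia and Schwann cell, meninges and dura, erythroid, myeloid and macrophage, endothelial and adipocyte. The last are immediate early and stress, mitochondrially encoded, cytosolic ribosomal protein and replication-dependent histone genes, of which 3 were measured. Alternatives were an estimated correlation and fry, which tests whether a list's genes move, on balance, in 1 direction. A further 11 marker lists were written after the first results were seen: trunk HOX, liver, kidney, lung, gut and pancreas, heart, eye and ear, fetal growth programme, bone-restricted matrix, lens and retina.

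The comparisons, tests, 25 lists and the rule for named genes were fixed before the data were examined. For the 3 main comparisons the rule took genes with adjusted p under 0.05, at least 1 CPM on average, groups that did not overlap and a symbol that is not a predicted name. Among these it took the 10 with the highest and the 10 with the lowest log2 fold change, or, where none passed, the 5 with the smallest p in each direction, given as not past the threshold. It also took Runx2, Hdac1, Hdac2, Hdac3, Sp7, Bglap, Ibsp, Spp1, Alpl and Col1a1, and up to 4 members with the smallest p of each list described. For the other comparisons it took the 5 with the smallest p in each direction where none passed. Genes named outside the rule are said to be so. Some genes that the rule takes are not reported here.

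Replicates of the vehicle groups with the same number deviated together from their group means (correlations across genes of 0.22, 0.752 and 0.812). Replicate 1 of each group went best with replicate 2 of the other, and replicate 3 with replicate 3. The numbers thus pair these 2 vehicle groups only in part by the data, and not by the labels. With a replicate block in the fit, as with none, 0 genes passed between them. In the other pairs of groups at least 1 of the correlations was below 0.1. No 2 libraries of a group were copies of each other, with chi-square per degree of freedom of 20.7 to 401.

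The gene tests were tried on simulated data with 200 genes changed, and the list test on 1 further simulation. Other steps, such as the splits and the tests of causes, were not tried on simulated data. At a 4-fold change edgeR recovered 54% in the comparison of vehicle groups, 55.5% in the drug comparison in WT and 52.5% in that in Runx2+/-, with 1.82% to 3.67% of calls false. At a 2-fold change it recovered 2%, 2% and 0%, with 0% of 4 calls false, 42.9% of 7 false and 0 calls made. In the WT drug comparison with the 4-fold change DESeq2 1.42.0 recovered 66% with 20% of calls false, and limma-voom 52.5% with 3.67% false. Camera called the 1 list that was raised 2-fold and no other of the 25. The genes were drawn independently of each other there, so this does not show how often camera calls unchanged lists of correlated genes.

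Alternatives were other scaling (RLE size factors or library size only), no filter or a stricter one, DESeq2, limma-voom with sample quality weights, only the groups compared, a replicate block, the level of Y-linked genes as a covariate, a threshold of 0.01 and leaving out each library. Those added after seeing the data were a fit without 3 libraries that stand apart from their group, a fit without 5 libraries with lens transcripts, a block with only the 2 vehicle groups, and removal of mitochondrially encoded genes before scaling. No library was left out of the results reported first.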

Results

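Transcript levels were measured by RNA sequencing in calvariae of mouse embryos at embryonic day 17.5. There were 3 libraries each of WT embryos of vehicle-treated dams, Runx2+/- embryos of vehicle-treated dams, WT embryos of MS-275-treated dams and Runx2+/- embryos of MS-275-treated dams. Reads assigned to no gene made up 13.5% ± 2.54 of uniquely aligned reads in WT vehicle, 15.0% ± 1.54 in Runx2+/- vehicle, 5.68% ± 0.546 in WT MS-275 and 12.4% ± 8.55 in Runx2+/- MS-275 (mean ± SD, n = 3). Counts in genes per library were 13307456 to 19044500 in WT vehicle, 16108108 to 17636311 in Runx2+/- vehicle, 16780972 to 19399760 in WT MS-275 and 15405004 to 17865741 in Runx2+/- MS-275. The first principal component held 72.5% of the variance and the second 9.66%. Replicate 3 of Runx2+/- MS-275 had a first-component score of −106, beside −108 and −111 in WT vehicle replicates 1 and 2, while the other 5 MS-275 libraries had scores of 83.9 to 140.03. Replicate 3 of WT vehicle (5.51) and replicate 3 of Runx2+/- vehicle (−14.5) stood apart from the other vehicle libraries.

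Runx2 (ENSMUSG00000039153), the transcription factor required for osteoblast formation and the gene that the genotype labels name, lies on chromosome 17 from 44495987 to 44814797 on the minus strand (GENCODE M21, GRCm38). Its level was 44.7 ± 1.97 CPM in WT vehicle and 52.0 ± 17.1 CPM in Runx2+/- vehicle, 110 ± 21.5 CPM in WT MS-275 and 70.5 ± 31.9 CPM in Runx2+/- MS-275 (mean ± SD, n = 3). The single libraries held 45.5, 42.4 and 46.1 CPM in WT vehicle and 65.3, 32.8 and 58.1 CPM in Runx2+/- vehicle. Those of WT MS-275 held 111, 131 and 88.2 CPM, and those of Runx2+/- MS-275 held 84.1, 93.5 and 34.1 CPM. Between the vehicle groups the log2 fold change of Runx2 was 0.22 (SE 0.36, 95% interval −0.60 to 1.04, edgeR adjusted p = 1.00), so the data did not show the lower level that a heterozygote could have. Between the MS-275 groups it was −0.64 (SE 0.36, 95% interval −1.47 to 0.18, edgeR adjusted p = 0.388), an interval that holds both no difference and the loss of 1 of 2 copies. A count per gene cannot tell the alleles apart, and reads outside the deleted part would still count, so the genotype is given below as labelled.

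**Figure D1:**
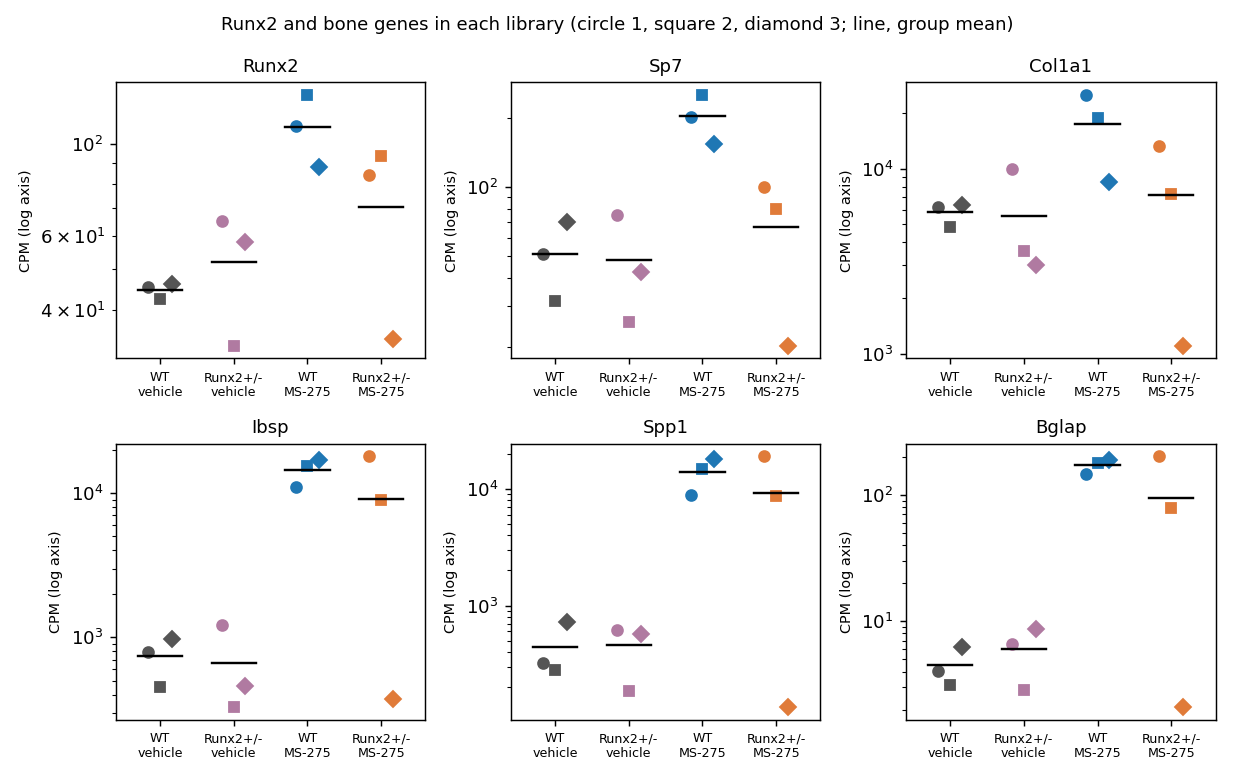
Runx2, Sp7, Col1a1, Ibsp, Spp1 and Bglap in each library, in CPM on log axes, by group, with circles, squares and diamonds for replicates 1, 2 and 3 and lines for group means. Runx2 averaged 44.7 CPM in WT vehicle and 110 CPM in WT MS-275, and the diamond of Runx2+/- MS-275 lies at 34.1 CPM.

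The comparison of vehicle groups asks which transcripts differ with the labelled genotype in the absence of the drug. Bone genes had log2 fold changes, libraries labelled Runx2+/- against WT, that were small beside their errors. The value was −0.09 (SE 0.55) for Sp7, an osteoblast transcription factor, and 0.42 (SE 1.01) for Bglap, which encodes osteocalcin. It was −0.15 (SE 0.97) for Ibsp, which encodes bone sialoprotein, and −0.07 (SE 0.81) for Col1a1, the main collagen of bone. Errors of this size leave open differences in either direction. The 14 adipocyte genes measured had a median log2 fold change of −1.48 and lay lower in all 14, with Pparg, the regulator of fat cell formation, at −1.47 (SE 0.52). This list stood at a mean log2 CPM of 4.77 and 3.75 in WT vehicle replicates 2 and 3, against 1.51 in WT vehicle replicate 1 and 1.59 to 1.99 in the libraries labelled Runx2+/-. Erythroid genes had a median of 0.49 and 15 of 16 lay higher, and meninges and dura genes a median of 0.47.

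No single gene passed in this comparison by edgeR (0 of 17967, with 55 at an unadjusted p under 0.05), and DESeq2 and limma-voom also gave 0. In 859 genes (4.78%) the groups did not overlap, where chance gives 10% for unpaired groups and shared deviations of replicates with equal numbers could lower that share. Among the genes with the smallest p, none past the threshold (edgeR adjusted p = 1.00), the level was higher for Pla2r1 (0.59), Cubn (1.62), Zkscan8 (0.34) and Tex15 (0.87), and lower for Cldn5 (−0.65), Bok (−0.47), Map2k2 (−0.37) and Yjefn3 (−0.92), on the log2 scale. With camera's preset correlation 8 lists passed. Meninges and dura (adjusted p = 0.0161) and erythroid (1.1e-04) were higher. Adipocyte (1.7e-14), skeletal muscle (median −0.30, 0.00164), endothelial (−0.16, 0.00542), osteoclast (−0.13, 0.0201), immediate early and stress (−0.17, 0.0349) and osteoblast (−0.08, 0.0349) were lower. No call held with an estimated correlation, where the adjusted p was 0.511 for adipocyte and 0.823 to 0.873 for the other 7. Adjusted over the list alone, 0 genes of any list passed. The adipocyte median was −0.75 without WT vehicle replicate 2. Leaving out 1 vehicle library turned the sign of 6 medians. Without WT vehicle replicate 3 the osteoblast median was 0.15, the osteoclast median 0.13, the endothelial median 0.07 and the immediate early median 0.06, and without WT vehicle replicate 2 they were −0.19, −0.23, −0.32 and −0.34 and the muscle median 0.06. The meninges and dura median was 0.29 without WT vehicle replicate 2 and 0.73 without replicate 3. Without Runx2+/- vehicle replicate 2 the median was 0.18 for osteoblast, 0.14 for osteoclast, −0.06 for endothelial, −0.07 for immediate early and 0.78 for meninges and dura genes. Leaving out replicate 1 of that group gave −0.52 for osteoblast, −0.42 for osteoclast, −0.60 for muscle, −0.26 for endothelial and −0.25 for immediate early genes, and leaving out WT vehicle replicate 1 −0.22 for osteoclast, −0.47 for muscle and −0.31 for endothelial genes. Without Runx2+/- vehicle replicate 3 the median was −0.09 for meninges and dura, −0.02 for muscle, 0.03 for osteoclast and −0.03 for osteoblast genes. The erythroid median was 0.28 without WT vehicle replicate 2 and 0.29 without Runx2+/- vehicle replicate 3.

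The comparison of WT MS-275 with WT vehicle asks what the drug changed in WT embryos. Genes of bone-forming cells rose. Bglap (ENSMUSG00000074483, chromosome 3, 88383501 to 88384464) went from 4.47 ± 1.63 to 171 ± 21.4 CPM (n = 3 each), a log2 fold change of 5.25 (SE 1.17, edgeR adjusted p = 0.0434). Spp1 (ENSMUSG00000029304), which encodes osteopontin, went from 439 ± 241 to 13920 ± 4740 CPM and Ibsp (ENSMUSG00000029306) from 741 ± 265 to 14414 ± 3034 CPM. Genes of the outer skin fell to near 0, as Dsp (desmoplakin, ENSMUSG00000054889) went from 339 ± 113 to 1.65 ± 1.10 CPM and Lor (loricrin, ENSMUSG00000043165) from 100.02 ± 56.4 to 0.753 ± 0.380 CPM. All of these differences, with the 3 libraries of each group not overlapping, were larger than the spread between replicates.

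Of 32 osteoblast and bone matrix genes 18 rose and 0 fell (25 adjusted over the list alone), with a median log2 fold change of 2.01. They included Sp7 (2.00, SE 0.57), Alpl, the phosphatase of mineralizing matrix (1.98, SE 0.59), Omd, which encodes osteomodulin (4.89), and Runx2 (1.30, SE 0.36), with an edgeR adjusted p of 0.0439 for Runx2 and 0.0447 for Sp7. Col1a1 did not pass (1.59, SE 0.83, edgeR adjusted p = 0.147). Among 18 mineralization and early osteocyte genes 6 rose, such as Phex (3.63) and Enpp1 (2.46), a pair of genes of phosphate and pyrophosphate handling, and Tnfsf11 (2.49), the osteoclast-inducing ligand RANKL (7 adjusted over the list alone). Of 20 osteoclast genes 6 rose (14 adjusted over the list alone), among them Ctsk, the collagen-degrading cathepsin K, from 152 ± 79.6 to 1419 ± 289 CPM. Chondrocyte genes rose in 3 of 19 (2 adjusted over the list alone), with Snorc at 3.61 and Hapln1 at 2.66. Camera with the preset correlation called all 4 lists higher (adjusted p = 2.8e-09, 0.00142, 1.7e-05 and 0.0147), and with an estimated correlation none (adjusted p = 0.566 for each). By fry the osteoclast list passed (adjusted p = 0.0396) and the osteoblast list did not (0.0574).

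Epidermal genes fell in 20 of 23 (23 adjusted over the list alone), with a median log2 fold change of −7.33, or −6.65 with the 3 genes that had no count in WT MS-275 set at their bound. The 10 most strongly lower genes by the naming rule had no count in any WT MS-275 library, so their folds are lower bounds against 3 counts per library. Klk7, a protease of the shedding skin surface (31.0 ± 15.6 CPM in vehicle), was at least 133-fold lower, Them5 113-fold, Lce1a1, of the cornified envelope, 100.33-fold, Kprp 94.7-fold and Casp14 85.0-fold. Lce1a2, Lce1c, Gsdma, Cysrt1 and Serpinb3b were at least 64.8-fold, 51.1-fold, 51.0-fold, 40.5-fold and 34.6-fold lower. Muscle genes fell in 7 of 24 (9 adjusted over the list alone, median −1.78), such as Ryr1, the calcium release channel (−3.84), and Pax7, of muscle stem cells (−3.09). Neuronal genes fell in 3 of 20 (Nefm −3.53, Nefl −2.62 and Satb1 −1.70, the same number adjusted over the list alone), with a median of −3.20. Glial and Schwann cell genes fell in 5 of 18 (6 lower and 1 higher adjusted over the list alone), with the myelin gene Mbp at −1.78. The muscle median was −2.87 without WT MS-275 replicate 1 and the neuronal median −4.81 without WT MS-275 replicate 3. Adipocyte genes fell in 2 of 14 (9 adjusted over the list alone), Cebpa (−1.73) and Dgat2 (−2.32).

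Camera with the preset correlation called these 5 lists lower (adjusted p = 1.2e-09 for epidermis, 1.7e-05 for muscle, 0.00168 for neuron, 0.00998 for glia and 0.0375 for adipocyte), and with an estimated correlation none (adjusted p = 0.566 for each). By fry the epidermis (adjusted p = 0.0290) and glia (0.0250) lists passed. Lens transcripts differed between the same libraries: Cryaa, a lens crystallin looked at after its values were seen, stood at 509, 476 and 5.39 CPM in WT vehicle and at 0.195, 0.982 and 0.604 CPM in WT MS-275. The mean log2 CPM of the epidermal list was 5.11 to 6.34 in WT vehicle and −0.67 to −0.63 in WT MS-275. That of the neuronal list was 6.36, 6.69 and 2.12 in WT vehicle and 2.01, 0.38 and 4.08 in WT MS-275.

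**Figure D2:**
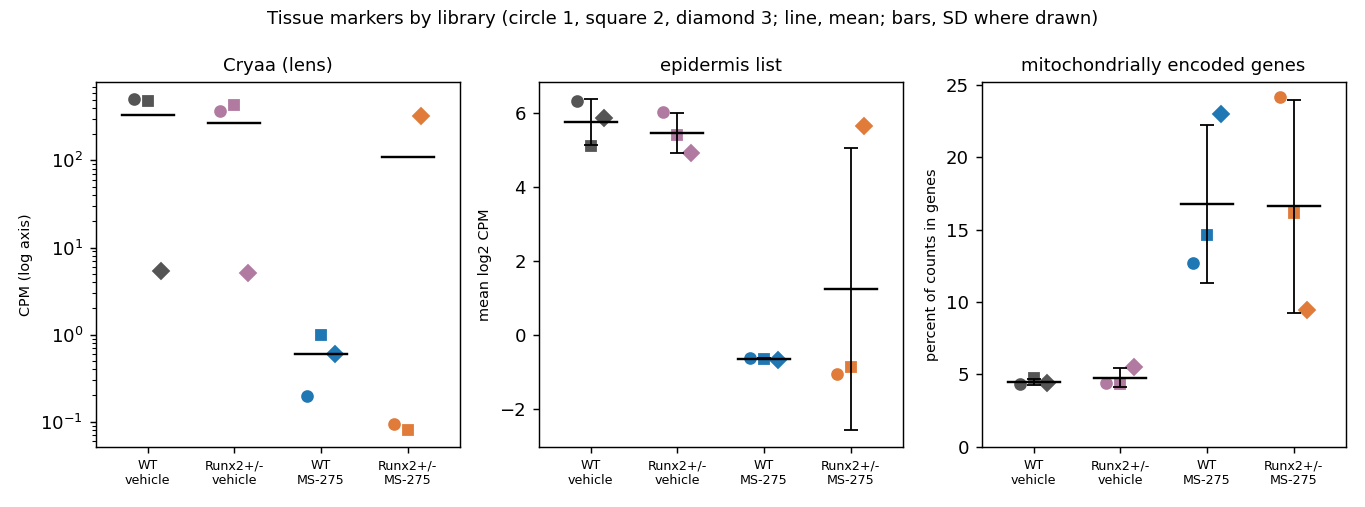
Cryaa in CPM on a log axis, the mean log2 CPM of the epidermal list, and the percent of counts in mitochondrially encoded genes, by group, with circles, squares and diamonds for replicates 1, 2 and 3, lines for means and bars for the SD in the other panels. Replicate 3 of Runx2+/- MS-275 holds Cryaa at 327 CPM and the epidermal list at 5.65, both within the span of the vehicle libraries, and a mitochondrial share of 9.48%, between those of the vehicle libraries and of the other MS-275 libraries.

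All 12 mitochondrially encoded genes measured rose in WT (median 2.84; 12 adjusted over the list alone), with mt-Nd1 from 2253 ± 162 to 15225 ± 8082 CPM. Their share of counts was 4.36%, 4.73% and 4.38% in WT vehicle and 12.7%, 14.6% and 23.0% in WT MS-275. Cytosolic ribosomal protein genes rose in 6 of 30 (21 adjusted over the list alone, median 1.66). Both lists passed camera with the preset correlation (adjusted p = 1.4e-08 and 2.8e-09) and neither did with an estimated one (adjusted p = 0.566 for each). By fry the mitochondrial list passed (adjusted p = 0.0250).

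Signalling genes went both ways in WT. FGF and hedgehog genes fell in 9 of 23 and rose in 1 (the same numbers adjusted over the list alone, median −0.35), the lower ones including the FGF targets Etv4 (−2.27), Spry2 (−1.58) and Spry4 (−0.99), and the higher one the receptor Fgfr3 (0.82). WNT genes rose in 5 and fell in 6 of 28 (5 and 7 adjusted over the list alone, median −0.02), with the inhibitor Wif1 at 2.93, Lef1 at −1.62 and Rnf43 at −2.23. BMP and TGF-beta genes rose in 5 and fell in 2 of 32 (11 and 3 adjusted over the list alone, median 0.66, which turned to −0.12 when scaled by library size only), with the inhibitor Bambi at 3.74 and the receptor Bmpr1b at −1.98. Suture and osteoprogenitor genes rose in 2 and fell in 1 of 28 (2 and 0 adjusted over the list alone, median 0.89): Alx4 (1.62) and Msx1 (1.35) rose and Axin2 (−1.16) fell. Camera called the BMP and TGF-beta list (adjusted p = 0.00700) and the suture list (0.00213) higher, in neither case with an estimated correlation (adjusted p = 0.566). It did not call the FGF and hedgehog (0.131) or WNT (0.949) list, whose medians were −0.14 and 0.30 without WT vehicle replicate 3, and the WNT median was −0.05 and −0.18 without WT vehicle replicates 1 and 2, −0.05, −0.01 and 0.03 without WT MS-275 replicates 1, 2 and 3 and −0.06 without Runx2+/- vehicle replicate 3.

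Hdac1, a target of the drug, lay higher without passing (log2 fold change 0.94, SE 0.30, edgeR adjusted p = 0.0501), as did Hdac2 (0.65, adjusted p = 0.0789 by edgeR), while Hdac3 stood at 0.05 and turned to −0.78 when scaled by library size only. Of the 11 HDAC genes 0 passed over all genes by edgeR, and 2 higher and 1 lower adjusted over the list alone. Genes of the HDAC-inhibitor response rose in 3 of 23 (2 adjusted over the list alone), Hist1h1c (1.75), Sat1 (1.31) and Hist1h2bc (a 2.83-fold change), with a list median of 0.29 that turned to −0.50 when scaled by library size only (camera adjusted p = 0.116). That median was 0.17 without WT MS-275 replicate 1, 0.45 without WT MS-275 replicate 3 and 0.52 without WT vehicle replicate 3. The HDAC family list did not pass either (0.911). Proliferation genes rose in 4 of 34 (Hmmr 1.52, Pcna 1.43, Kif20a 1.18 and Cenpe 0.91, and 0 adjusted over the list alone, median 0.40, or −0.44 when scaled by library size only). Camera called that list higher (adjusted p = 0.00168), but not with an estimated correlation (adjusted p = 0.566). In the apoptosis and p53 list Fas (1.53) and Ccng1 (1.46) rose and Perp, also a gene of skin cell junctions, fell (−2.93), the same numbers adjusted over the list alone, with a median of 0.29, or −0.50 when scaled by library size only (camera adjusted p = 0.335). The apoptosis and p53 median was 0.14 without WT MS-275 replicate 1 and 0.17 without WT vehicle replicate 1.

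Among the remaining lists in WT, 3 of 14 meninges and dura genes rose, Dcn (2.98), Lum (3.38) and Ogn (2.88), matrix proteoglycan genes that bone also expresses, and Rdh10 fell (−1.12), with 6 higher and 1 lower adjusted over the list alone and a median of 1.74. Myeloid genes rose in 3 of 19 (Cd68 1.55, Ptprc 1.35 and Cd14 1.66, and 0 adjusted over the list alone, median 1.34), and 1 of 18 endothelial genes, Emcn (2.30), rose (0 adjusted over the list alone, median 0.42, or −0.37 when scaled by library size only). The endothelial median was 0.28 without WT MS-275 replicate 1 or 2 and 0.64 without replicate 3. Camera called these 3 lists higher (adjusted p = 0.0264, 0.0172 and 0.0175), and with an estimated correlation none (adjusted p = 0.566 for each). In lists that did not pass, Slc4a1 (−1.62) was the 1 erythroid gene to fall (0 adjusted over the list alone, median −0.24 and mean 0.05, camera adjusted p = 0.949), and the median was −0.01 without WT MS-275 replicate 1, −0.36 without WT MS-275 replicate 3 and −0.02 without WT vehicle replicate 2. Hspa1b (−2.07) and Egr3 (−1.63) were the 2 immediate early genes to fall (2 adjusted over the list alone, median −0.18, 0.369), and that median was −0.33 and 0.16 without WT vehicle replicates 2 and 3 and −0.50 and −0.02 without WT MS-275 replicates 1 and 3. Hist1h1c was the 1 of 3 histone genes to rise (1 adjusted over the list alone, median 1.06, 0.140), with a median of 0.56 without WT vehicle replicate 2 and 1.78 without WT vehicle replicate 3.

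In all, edgeR called 3414 of 17967 genes in WT, 1738 higher and 1676 lower, or 526 and 7009 when scaled by library size only, which moved the median log2 fold change of all genes from −0.13 to −0.95. Other genes with the highest folds were Bglap2 (5.23), Lipc (4.93), Lgals2 (4.88), Wfdc6a (4.82) and Timp1, an inhibitor of matrix proteases (4.20). In 9838 genes (54.8%) the groups did not overlap, where chance gives 10%. Every called gene had an adjusted p of at least 0.0434 by edgeR, and the count was 0 without any 1 of 8 libraries (WT vehicle 1 or 2, Runx2+/- vehicle 1 or 2, the 3 WT MS-275 libraries or Runx2+/- MS-275 2), 2021 without Runx2+/- vehicle 3, 5578 without Runx2+/- MS-275 1, 5601 without WT vehicle 3 and 8480 without Runx2+/- MS-275 3, and also 0 with no filter, with a replicate block or with the Y-linked covariate. Without the 5 libraries with Cryaa above 10 CPM, chosen after seeing the data and leaving 1 library in each vehicle group, 1460 genes passed, 1147 of them among the 3414, with 18 of 32 osteoblast genes higher (median 1.65), 21 of 22 epidermal genes lower (−7.31) and 2 of 20 neuronal genes lower (median 0.89).

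**Figure D3:**
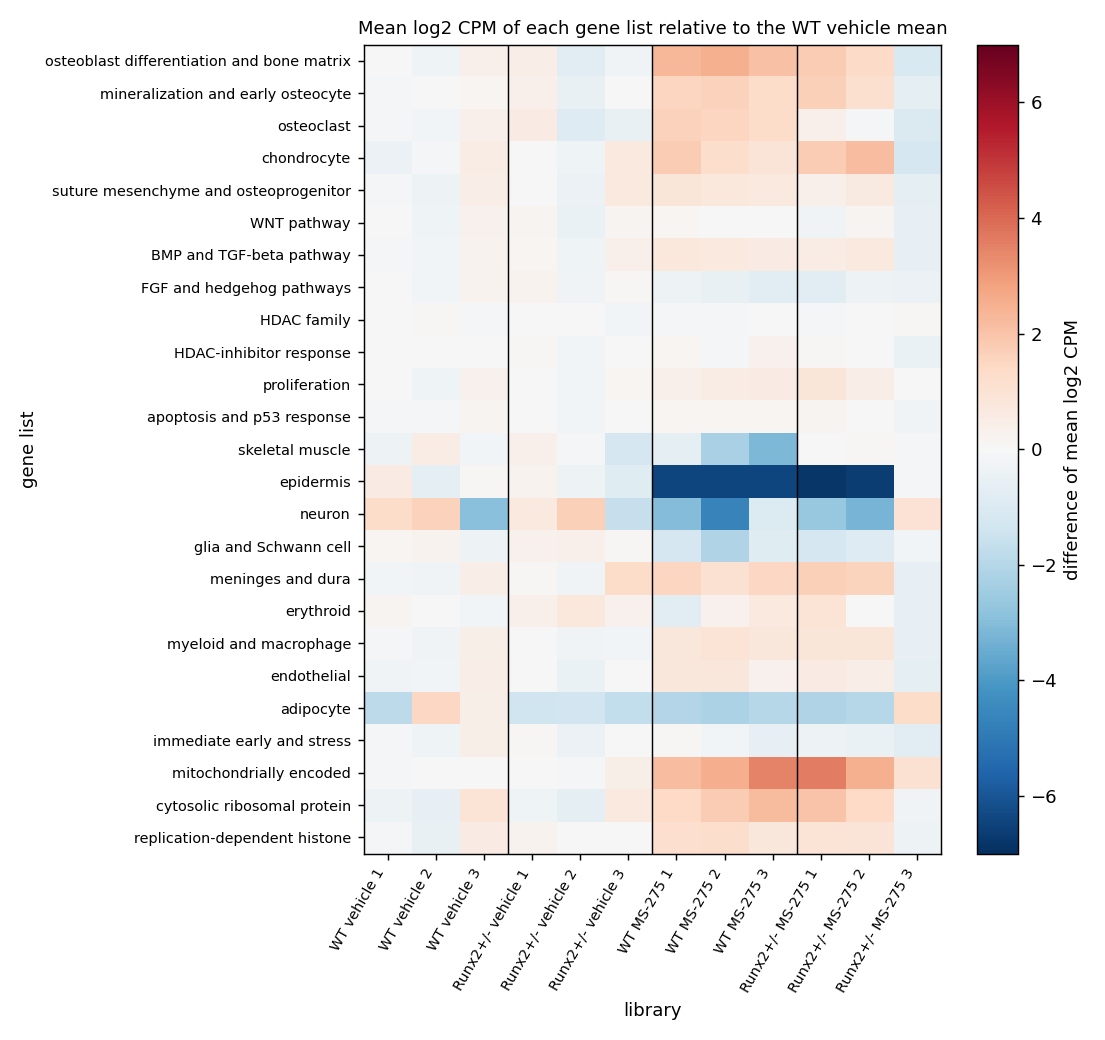
Mean log2 CPM of each of the 25 gene lists in each of the 12 libraries, as the difference from the mean of the WT vehicle libraries (red higher, blue lower). The epidermal list stands at −0.67 to −0.63 in WT MS-275 and at 5.65 in replicate 3 of Runx2+/- MS-275 before the difference is taken; smaller shifts, such as those of the proliferation and BMP lists in WT, turn negative when scaled by library size only.

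The same question in the libraries labelled Runx2+/- gave bone genes with high but uneven levels. With MS-275 Bglap stood at 94.3 ± 101 CPM (6.02 ± 2.90 with vehicle), a log2 fold change of 3.97 (SE 1.10, edgeR adjusted p = 0.181), with Ibsp at 3.77 (SE 1.09) and Spp1 at 4.34 (SE 1.28). Runx2 stood at 0.44 (SE 0.36), Sp7 at 0.48 (SE 0.55), Alpl at 0.48 (SE 0.57) and Col1a1 at 0.39 (SE 0.81). The mean log2 CPM of the osteoblast list was 7.95, 7.51 and 5.10 in the 3 MS-275 libraries, and 5.41 to 6.64 in the vehicle libraries. The epidermal list stood at −1.06, −0.88 and 5.65, and Cryaa, looked at after its values were seen, at 0.0929, 0.0798 and 327 CPM, the last of each in replicate 3. Mitochondrially encoded genes took 24.2%, 16.2% and 9.48% of counts, against 4.32% to 5.52% with vehicle.

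With all 12 libraries 0 genes passed by edgeR, with 3782 at an unadjusted p under 0.05, while DESeq2 called 1280 and limma-voom 10539. In 2676 genes (14.9%) the groups did not overlap, where chance gives 10%. The genes with the smallest p, none past the threshold (edgeR adjusted p = 0.181), were higher for Mir99ahg (1.61), Slc36a2 (2.14), Hadhb and Idh3g, enzymes of fatty acid oxidation (a 2.83-fold difference) and the citric acid cycle (1.02), and Lgals2 (4.24), and lower for Atf5 (−1.45), Hnrnpa0 (−1.03), Tada2b (−0.97), Rab35 (−0.74) and Pithd1 (−0.94). Camera with the preset correlation called 6 lists higher. These were osteoblast (median 0.61, 8 adjusted over the list alone, adjusted p = 0.00944), mineralization (0.82, 3, 0.0366), proliferation (0.52, 7, 1.1e-04), myeloid (1.00, 0, 0.0233), mitochondrially encoded (2.67, 12, 2.8e-11) and ribosomal protein genes (1.32, 0, 8.0e-08). The osteoblast median turned to −0.11 and the proliferation median to −0.06 when scaled by library size only. It called 5 lists lower, FGF and hedgehog (−0.27, 0.00408), epidermis (−1.38, 3.9e-10), neuron (−1.05, 0.00538), glia (−1.07, 0.0130) and immediate early (−0.35, 0.0189). No call held with an estimated correlation (adjusted p = 0.847 for each). Without replicate 3 of Runx2+/- MS-275 the median was −6.96 for epidermis, −3.55 for neuron, 1.06 for osteoblast and 1.52 for mineralization genes, and without replicate 1 of that group it was −0.80, −0.58, 0.21 and 0.41. Without replicate 1 of that group it was also 0.31 for proliferation, 0.84 for ribosomal protein and −0.68 for glial genes, and without replicate 2 it was −0.58 for FGF and hedgehog, −0.80 for epidermis and −0.53 for neuron. Leaving out Runx2+/- vehicle replicate 1 gave 1.27 for osteoblast, 1.41 for mineralization and −0.23 for immediate early genes, replicate 2 of that group −0.23 for neuron and replicate 3 0.40 for osteoblast genes.

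Leaving out replicate 3 of Runx2+/- MS-275, edgeR called 5955 genes in this comparison, 3367 higher and 2588 lower. Runx2 then rose (0.77, SE 0.27, edgeR adjusted p = 0.0495), as did Bglap (4.55, SE 0.51), Ibsp (4.34, SE 0.64), Spp1 (4.92, SE 0.70), Phex (3.42) and mt-Nd1 (3.13), and Dsp fell (−5.43), while Sp7 (0.92, edgeR adjusted p = 0.121) and Col1a1 (0.89, edgeR adjusted p = 0.265) did not pass. Of the lists, 15 of 32 osteoblast, 18 of 34 proliferation, 12 of 12 mitochondrial and 20 of 30 ribosomal protein genes rose, and 22 of 23 epidermal genes fell.

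The drug differences in the 2 genotypes, which share no library, had a Pearson correlation of 0.875 and a Spearman correlation of 0.845 across 17967 genes, which are not independent replicates, and 83.9% of genes had the same sign. With all libraries 0 genes passed in both genotypes by edgeR, since 0 passed in Runx2+/- (3782 there at an unadjusted p under 0.05), while DESeq2 gave 1013 and limma-voom 9482. Leaving out replicate 3 of Runx2+/- MS-275, 2977 genes were higher in both (747 for independent lists) and 2185 lower in both (631 for independent lists). Vehicle replicates with equal numbers deviated together across the genotypes (correlations of 0.22, 0.752 and 0.812). Both vehicle groups also held lens and skin transcripts that most MS-275 libraries lacked. Each could raise the correlation and the overlaps by an amount not tested, so these do not part a drug effect from tissue content.

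**Figure D4:**
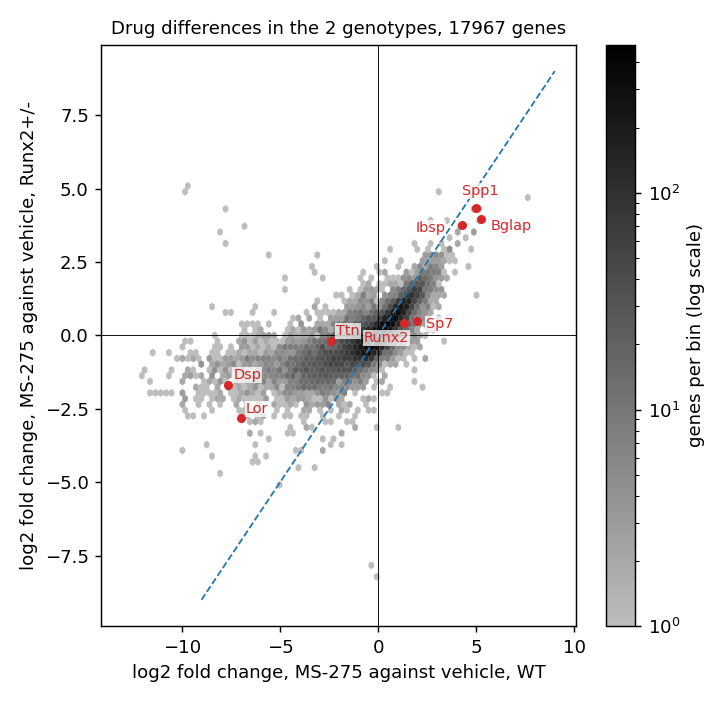
Log2 fold change of each of 17967 genes with MS-275 against vehicle, in WT (horizontal axis) and in Runx2+/- (vertical axis), with shading for genes per bin, red points for named genes and a dashed line where both are equal. Bglap lies at 5.25 and 3.97 and Dsp at −7.65 and −1.67; Sp7 lies at 2.00 and 0.48, and genes at 0 counts in 1 group have fitted values that are not folds.

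The interaction asks whether the drug difference depended on the labelled genotype. No gene passed by edgeR (0, with 953 at an unadjusted p under 0.05), while DESeq2 called 38 and limma-voom 609. Runx2 stood at −0.86 (SE 0.51), Sp7 at −1.51 (SE 0.79), Alpl at −1.50 (SE 0.81), Bglap at −1.28 (SE 1.41) and Ibsp at −0.51 (SE 1.38), with edgeR adjusted p of 0.873 or more. The smallest p among higher genes, none past the threshold (edgeR adjusted p = 0.873), belonged to Rasd2, which had no count in WT MS-275, Isl1 (4.59), Apoc1 (2.19), Epcam (3.14) and Pou4f3 (5.07), and among lower ones to Chac1 (−2.24), Atf5 (−0.97), Ncf4 (−2.07), Klhl33 (−2.63) and Akr1c18 (−3.27). Camera with the preset correlation called 11 lists, among them osteoblast (median −1.07, adjusted p = 6.5e-12) and osteoclast (−1.50, 4.8e-12) lower and muscle (2.05, 3.8e-19) and epidermis (5.97, 8.5e-05) higher, and with an estimated correlation none (adjusted p = 0.467 to 0.676). Without replicate 3 of Runx2+/- MS-275 the epidermal median was 0.03 and the osteoblast median −0.69, without Runx2+/- vehicle replicate 1 the osteoclast median was −0.93, and without WT MS-275 replicate 1 the muscle median was 3.12. In all, 7 lists passed without replicate 3 of Runx2+/- MS-275, and without WT vehicle 3 or Runx2+/- vehicle 2, 17 did. Without replicate 1 of Runx2+/- MS-275 edgeR called 1 gene.

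Under the drug, the comparison of Runx2+/- MS-275 with WT MS-275 asks how the labelled genotypes differ when both are treated. Osteoblast genes lay lower in all 32 (median log2 fold change −1.18), as Dlx5, a regulator of bone formation, at −1.08 (SE 0.23) and Sp7 at −1.61 (SE 0.57). Osteoclast genes lay lower in 19 of 20 (median −1.61), with the receptor Calcr at −2.02 (SE 0.53). Epidermal genes lay higher in all 23 (median 5.62, or 4.66 with 3 genes at their bound), the list standing at 5.65 in replicate 3 of Runx2+/- MS-275 and at −1.06 and −0.88 in the other 2. Without that replicate the median was −0.13 for epidermis and −0.78 for osteoblast genes. By edgeR 0 genes passed, with 2832 at an unadjusted p under 0.05, while DESeq2 called 702 and limma-voom 3019, and in 2993 genes (16.7%) the groups did not overlap, where chance gives 10%. The smallest p, not past the threshold (edgeR adjusted p = 0.265), belonged among higher genes to Rasd2 (at least 3.36-fold higher against no count in WT MS-275), Abca8b (1.19), Epcam (3.44), Isl1 (4.86) and Pou4f3 (5.59), and among lower ones to Chac1 (−2.84), Ncf4 (−2.31), Mgll (−0.96), Snx10 (−1.33) and Gpr137b (−1.01).

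Camera with the preset correlation called 10 lists lower in that comparison, with adjusted p from 4.5e-14 for osteoblast and osteoclast to 0.0343 for myeloid, the others being mineralization (−0.42), suture (−0.52), BMP and TGF-beta (−0.36), HDAC-inhibitor response (−0.44), endothelial (−0.33), immediate early (−0.37) and ribosomal protein genes (−0.50). It called 5 higher, muscle (1.77, 1.1e-13), epidermis (0.00103), neuron (1.93, 0.0275), glia (0.81, 0.0358) and adipocyte (1.30, 0.0343). With an estimated correlation none passed (adjusted p = 0.432 for osteoclast and up to 0.740). Adjusted over the list alone, 14 osteoclast and 5 osteoblast genes were lower and 14 muscle and 20 epidermal genes higher. Without replicate 3 of Runx2+/- MS-275 the median was 0.00494 for adipocyte (all of whose 14 genes lay higher with it), −0.54 for neuron, 0.30 for glia, 0.16 for myeloid, −0.16 for mineralization, −0.24 for suture, −0.12 for BMP and TGF-beta, −0.23 for HDAC-inhibitor response, −0.13 for endothelial, −0.19 for immediate early and −0.09 for ribosomal protein genes, and the muscle median was 2.82 without WT MS-275 replicate 1. Leaving out WT MS-275 replicate 3 gave 3.73 for neuron and −0.25 for ribosomal protein genes, Runx2+/- MS-275 replicate 1 −1.13 for mineralization, −0.72 for myeloid and −0.98 for ribosomal protein genes, and replicate 2 of that group −0.86 for suture, −0.60 for BMP and TGF-beta and −0.54 for myeloid genes. Then 5 lists passed without replicate 3 of Runx2+/- MS-275 and 0 genes by edgeR, and without replicate 1 of that group 23 genes did.

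Set against WT vehicle, the libraries labelled Runx2+/- with MS-275 had Bglap at 4.39 (SE 1.13), Ibsp at 3.62 (SE 1.08) and Spp1 at 4.40 (SE 1.29), with edgeR adjusted p of 0.129 to 0.130. By edgeR 0 genes passed, with 4284 at an unadjusted p under 0.05, while DESeq2 called 2078 and limma-voom 12207, and in 3244 genes (18.1%) the groups did not overlap, where chance gives 10%. The smallest p belonged among higher genes to Mir99ahg (1.79), Uggt2 (1.05), mt-Atp8 (3.24), Lgals2 (4.31) and Ganc (0.94), and among lower ones to Rab35 (−0.89), Atf5 (−1.29), Fscn1 (−1.50), Hnrnpa0 (−1.16) and Rnf187 (−1.01), none past the threshold. Camera with the preset correlation called proliferation (0.50, or −0.03 when scaled by library size only), mitochondrially encoded (2.71, 12 adjusted over the list alone) and ribosomal protein genes (1.21) higher and FGF and hedgehog (−0.24), epidermis (−1.76), neuron (−1.09) and immediate early genes (−0.62) lower (adjusted p from 9.6e-11 for mitochondrially encoded genes to 0.0263 for neuron). With an estimated correlation none passed (adjusted p = 0.985 for each). With replicate 3 of Runx2+/- MS-275 left out, edgeR called 6513 genes and camera 13 lists, with a median of −7.37 for epidermis and −3.84 for neuron. Without replicate 1 of that group the proliferation median was 0.26 and the ribosomal protein median 0.68, and without WT vehicle replicate 3 the FGF and hedgehog median was −0.09, the immediate early median −0.31, the neuron median −1.66 and the ribosomal protein median 1.83. Leaving out WT vehicle replicate 2 gave −0.38 for FGF and hedgehog and −0.60 for neuron, and Runx2+/- MS-275 replicate 2 −0.49 and −0.62.

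Whether the drug moved back what differed with the labelled genotype was counted as genes past the threshold in both steps in opposite directions. By edgeR the count was 0, since 0 genes passed between the vehicle groups (55 at an unadjusted p under 0.05), and it was 0 by DESeq2 and limma-voom. The genotype difference with vehicle and the drug difference in Runx2+/-, which share 3 libraries, had a Pearson correlation of −0.171, a Spearman correlation of −0.045 across genes and a covariance of −0.045. In 20 simulations of unchanged groups the Pearson correlation was −0.498 and the covariance −0.159, but these drew the libraries independently, while vehicle replicates with equal numbers deviated together. Taken from the deviations of the replicates, unchanged groups would have a correlation of −0.345 and a covariance of −0.131 without that pairing, and −0.106 and −0.0223 with it. The genotype differences with vehicle and with MS-275, which share no library, had a Pearson correlation of 0.193.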

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

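The tests on bone genes moving alike, on skin, on mitochondrial genes and on the bone, skin and nerve genes without the libraries with lens transcripts were chosen after the result was seen, as were the fits without the libraries that stand apart and the repeats of the Runx2 ratio with libraries left out. The others below were set down before their value was computed.

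In WT, bone genes were higher and skin genes lower with MS-275, as were some nerve (3 of 20) and muscle genes (7 of 24). The list calls did not hold with an estimated correlation. Less of other tissue around the same bone would raise genes alike if bone alone expressed them. Of the 9 genes listed as bone-restricted, 8 parted WT MS-275 from WT vehicle after division by their common level. On that log2 scale Bglap was up by 1.81, with Sp7 at −1.42 and Smpd3 at −2.40. This argues against it as the whole cause only if the other tissue expresses none of these genes. That was not tested and is in doubt for Smpd3. Relative to the common level it stood at 1.74 to 2.53 in vehicle libraries with the neuronal list at 5.73 to 6.74. In those with that list at 2.12 and 3.46 it stood at 1.59 and 0.976. The common level includes Smpd3, so the shifts of the other genes also rest on it. Skin on the vehicle calvariae stays open for the epidermal genes, since their list stood at 5.65 (mean log2 CPM) in the 1 MS-275 library that lay with the vehicle libraries, above the lowest vehicle library at 4.94, and dissection cannot be told apart from the drug in these groups. Without the 5 libraries with lens transcripts the WT median was 1.65 for osteoblast and −7.31 for epidermal genes, which goes against eye tissue as the whole cause for these genes. But 1 WT vehicle library was left, replicate 3, which stands apart from its group, so eye tissue is not excluded. For nerve genes it stays open, as their median turned to 0.89 there. The lowest WT vehicle library held 1.21 times the lens list and 0.790 times the retina list of the highest WT MS-275 library (means 6.56 and 4.81 times). Cryab alone held 51.7 of the 63.9 CPM of the lens list in WT MS-275, which lowers the lens ratios. For the eye and ear list, already seen before this test was set down, the same ratios were 3.20 and 27.2 times. A drug effect on bone and skin, and a different part of the bone, were not tested apart from these.

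Replicate 3 of Runx2+/- MS-275 lay with the vehicle libraries. Skin and nerve tissue diluting a bone profile changed by the drug would leave the proportions of the 9 bone genes near those of the other MS-275 libraries, if that tissue expresses none of them. The proportions lay 3.32 times farther from these (distances of 3.31 to 5.88) than from the vehicle libraries (0.571 to 2.18). This argues against such dilution only on that condition, which was not tested and is in doubt for Smpd3. The proportion of Smpd3 was 1.74 to 2.53 in vehicle libraries with the neuronal list at 5.73 to 6.74. It was 1.59 and 0.976 in those with that list at 2.12 and 3.46. In replicate 3 of Runx2+/- MS-275 these values were 2.11 and 6.05, so the distances do not decide on dilution. A vehicle sample under an MS-275 label may account for it. In this library 39.6% of genes lay outside the range of the 6 vehicle libraries, against 61.5% to 70.5% in the other MS-275 libraries. Each vehicle library was set against the other 5 and this library together, which ties its share to the one in question. The 39.6% is below WT vehicle replicate 3 alone (53.8%) and above the other 5 vehicle libraries (9.09% to 31.3%). The comparison therefore rests on WT vehicle replicate 3, and the label stays open. The mitochondrial share of replicate 3 of Runx2+/- MS-275 (9.48%) and its share of reads assigned to no gene (22.2%) lay outside the vehicle range. An embryo that did not respond to the drug was not tested and stays open.

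With vehicle, Runx2 was not lower in the libraries labelled Runx2+/- (log2 fold change 0.22), and with MS-275 it lay lower without passing (−0.64, 95% interval −1.47 to 0.18). Different bone content might hide a lower level, but Runx2 relative to the rest of the osteoblast list was higher by 0.60 in these libraries than in WT within treatments (log2 scale, 95% interval 0.00059 to 1.195, two-sided exact permutation p = 0.02 over 400 splits). Without replicate 3 of Runx2+/- MS-275 it was 0.38 (−0.004 to 0.77), and without the 3 libraries that stand apart 0.24 (−0.149 to 0.62), with 0.0455 for vehicle alone, and leaving out any 1 library except Runx2+/- MS-275 replicate 1 (0.78, 0.297 to 1.27) brought the lower limit below 0, so whether the ratio is higher stays open. All of these intervals lie above −1. But the ratio fell as the list rose, at −0.989 to −0.465 in WT vehicle and −1.80 to −1.65 in WT MS-275. The mean log2 CPM of the list was 5.86 to 6.49 and 8.21 to 8.63 there. It was 7.95, 7.51 and 5.10 in Runx2+/- MS-275, a lower level that would itself raise the ratio. The ratio therefore does not remove bone content and cannot decide whether bone content hides the loss of 1 of 2 copies. The list may also fall with Runx2, which drives many of its genes. The genotype labels, transcripts from the targeted allele and a rise from the intact allele were not tested, and counts per gene cannot part the alleles.

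The drug difference and the labelled genotype interacted in 11 gene lists by camera with the preset correlation, and in 0 with an estimated correlation. The median interaction log2 fold change was −1.07 for osteoblast, −0.43 for mineralization, −1.50 for osteoclast, −0.60 for suture, −0.49 for BMP and TGF-beta and −0.36 for HDAC-inhibitor response genes. It was 2.05 for muscle, 5.97 for epidermis, −0.65 for meninges, 2.24 for adipocyte and −0.39 for ribosomal protein genes. Without replicate 3 of Runx2+/- MS-275 it was 0.03 for epidermis, −0.69 for osteoblast, 1.33 for adipocyte, −0.12 for mineralization, −0.32 for suture, −0.20 for BMP and TGF-beta, −0.16 for HDAC-inhibitor response, −0.28 for meninges and 0.02 for ribosomal protein genes, so this library carries the epidermal value. Without WT MS-275 replicate 1 it was 3.12 for muscle, without replicate 2 −0.13 for mineralization and without replicate 3 −0.14 for ribosomal protein genes. Without Runx2+/- vehicle replicate 1 it was −0.93 for osteoclast, −0.71 for osteoblast and −0.13 for mineralization genes, and without replicate 2 −0.65 for ribosomal protein genes. Leaving out Runx2+/- vehicle replicate 3 gave −0.31 for suture, −0.23 for BMP and TGF-beta, −0.15 for HDAC-inhibitor response, −0.18 for meninges and 0.11 for ribosomal protein genes. Leaving out Runx2+/- MS-275 replicate 1 gave −1.63 for osteoblast, −0.95 for mineralization, −1.15 for meninges and −0.92 for ribosomal protein genes, and replicate 2 −1.03 for meninges. The ribosomal protein median was −0.18, −0.11 and −1.06 without WT vehicle replicates 1, 2 and 3, the mineralization median −0.24 without replicate 1 and the HDAC-inhibitor response median −0.64 without replicate 3. Of 40 splits of the libraries, 25 gave at least as many lists (real 11, highest other 20). These splits shuffled the labels across both genotype and treatment, so they also broke up the drug difference. They therefore cannot test the interaction apart from the drug, and chance is not excluded for the lists. For genes 40 gave at least as many (real 0, highest other 0), which any split must when the real count is 0, so that count tests nothing.

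Siglec15, an osteoclast gene, lay higher with MS-275 in WT (2.15, edgeR adjusted p = 0.0524) and lower in Runx2+/- (−1.82, edgeR adjusted p = 0.229) without overlap of the libraries and past the threshold in neither, with an interaction of −3.97 (edgeR adjusted p = 0.873). Apoc1 lay apart between the labelled genotypes in opposite directions with and without the drug, with an interaction of 2.19 (edgeR adjusted p = 0.873). Among 351 lists and named genes examined, these were 1 each, where a 10% share without overlap in each comparison would give about 1.76 of each kind by chance. Over all genes that share was 4.78% between the vehicle groups and 16.7% between the MS-275 groups. For the drug it was 54.8% in WT and 14.9% in Runx2+/-. The named genes were also chosen in these data by small p or large fold, some for groups that did not overlap. A 10% share does not apply to genes chosen in this way, so the 1.76 cannot serve as a chance value.

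Reads not counted in any gene differed between vehicle and MS-275 libraries. Reads assigned to no gene made up 5.21% to 8.65% of uniquely aligned reads in 5 MS-275 libraries, below all 6 vehicle libraries (10.53% to 16.8%), and 22.2% in replicate 3 of Runx2+/- MS-275, above them. In the same 5 MS-275 libraries ambiguous reads made up 4.12% to 4.78%, above the vehicle libraries (3.25% to 4.07%). Reads with more than 1 alignment made up 20.1% of all reads in WT MS-275 replicate 3 and 18.9% in Runx2+/- MS-275 replicate 1 (14.0% to 18.2% with vehicle). In the remaining MS-275 libraries they made up 15.07% to 17.92%, within the vehicle range. The cause of these differences was not tested. In WT the shares of reads assigned to no gene and of ambiguous reads go with the drug, while those of reads with more than 1 alignment overlap between the groups.

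With 3 libraries against 3 there are 10 splits, too few to give a share under 0.05. For WT MS-275 against WT vehicle, 1 split gave as many genes (real 3414, highest other 0) and 2 as many lists (real 17, highest other 20). For the vehicle groups 10 gave as many genes (real 0, highest other 0) and 10 as many lists (real 8, highest other 15), and among the 4 splits that part every pair of equal numbers the highest other was 13 lists. For MS-275 against vehicle in Runx2+/-, 10 gave as many genes (real 0, highest other 6162) and 7 as many lists (real 11, highest other 18). For Runx2+/- MS-275 against WT MS-275, 10 gave as many genes (real 0, highest other 0) and 8 as many lists (real 15, highest other 19). For Runx2+/- MS-275 against WT vehicle, 10 gave as many genes (real 0, highest other 7153) and 9 as many lists (real 7, highest other 18). The splits with 6162 and 7153 genes put replicate 3 of Runx2+/- MS-275 with vehicle replicates 1 and 2, which points to a structure of the samples.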

How the results depend on the processing

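The fits without the 3 libraries that stand apart (replicate 3 of WT vehicle, Runx2+/- vehicle and Runx2+/- MS-275), without the 5 libraries with lens transcripts and with mitochondrial genes removed, and the block with only the vehicle groups, were chosen after seeing the data; where a vehicle group kept 1 library, it is assumed to vary like the other groups. The count of 0 between the vehicle groups, and of genes changed back by the drug, was 0 in all alternatives run. For WT MS-275 against WT vehicle (3414) the count was 3311 with RLE size factors, 3667 with a stricter filter and 3501 with mitochondrial genes removed, but 7535 with library size only (526 higher, 7009 lower), 0 with no filter, 0 at a threshold of 0.01, 7223 with DESeq2, 14248 with limma-voom, 7309 with only the groups compared and 0 with the Y-linked covariate. With a replicate block it was 0; the numbers do not pair these groups (correlations −0.409 to −0.042), and with the block gene counts elsewhere stayed at 0. It was 0 to 8480 leaving out 1 library, 10887 without the 3 libraries and 1460 without the 5. The called genes' adjusted p lie just under 0.05, so small changes of the fit move them together across it.

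Counts of 0 elsewhere moved as follows. For MS-275 in Runx2+/- DESeq2 gave 1280, limma-voom 10539, leaving out 1 library 0 to 5955, leaving out the 3 libraries 9543 and the 5 libraries 614. For Runx2+/- MS-275 against WT MS-275 these were 702, 3019, 0 to 23 and 1 (without the 3). Against WT vehicle they were 2078, 12207, 0 to 6513, 9684 and 1569. For the interaction they were 38, 609 and 0 to 1 (leaving out 1 library). For genes changed in both genotypes they were 1013, 9482, 0 to 5162, 8477 and 486. The cause of the differences between tools was not tested.

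Lists called fell to 0 with an estimated correlation in all 6 comparisons, and by fry to 4 in WT MS-275 against WT vehicle and 0 in the other 5. For the vehicle groups 2 lists passed without the 3 libraries and 13 without the 5. For Runx2+/- MS-275 against WT MS-275 it was 5 without replicate 3 of Runx2+/- MS-275, 5 without the 3 and 5 without the 5 libraries. Against WT vehicle it was 13, 13 and 11, and for the interaction 7 to 17 leaving out 1 library and 6 without the 3; the cause was not tested. With library size only, which lowers the drug folds, 28 named-gene results changed sign, 2 of which passed with one scaling or the other, Ostm1 (−0.091) and Hdac3 (−0.78) in WT, and 26 with neither, among them Hdac2 in WT (−0.22) and Runx2 (−0.21), Sp7 (−0.27), Alpl (−0.27) and Col1a1 (−0.48) in Runx2+/-. In the other alternatives 112 results changed sign at least once, none that passed in either fit. Of the named-gene results 97 lost the threshold with the block, no filter or the Y-linked covariate, and 196 passed it with DESeq2 and 319 with limma-voom. With 3 libraries a group, 2-fold changes were mostly missed (2% recovered in the simulation of the WT drug comparison).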

Other observations

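The tests on trunk tissue and on developmental age were set down before their value was computed; that on mitochondrial genes, the added marker lists and the trunk ratio with a library left out were chosen after the result was seen.

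Transcripts of tissues outside the skull vault were present at levels that varied between libraries. Summed eye and ear markers, with lens crystallins such as Cryaa and Cryba1 the highest in WT vehicle, stood at 723 ± 540 CPM in WT vehicle, 614 ± 443 in Runx2+/- vehicle, 26.6 ± 4.15 in WT MS-275 and 281 ± 419 in Runx2+/- MS-275 (n = 3 each). Lens markers stood at 419 ± 287, 346 ± 242, 63.9 ± 8.39 and 174 ± 109 CPM, and retina markers averaged 22.3 CPM in WT vehicle, 30.4 in Runx2+/- vehicle, 4.63 in WT MS-275 and 14.3 in Runx2+/- MS-275. Of the 15 lens genes 5 had at least 1 CPM in WT MS-275, chiefly Cryab at 51.7 CPM. Tecta, an inner ear gene chosen after its values were seen, stood at 56.5 CPM in WT vehicle replicate 3 and 55.4 in Runx2+/- vehicle replicate 3, against 3.75 to 15.1 in the other vehicle libraries and at most 6.06 with MS-275. Liver markers stood at 185 ± 147, 614 ± 358, 234 ± 395 and 358 ± 479 CPM in the same order of groups, heart markers at 132, 102, 78.8 and 239.5, kidney markers at 21.6, 34.5, 13.6 and 22.2, lung markers at 8.85, 7.81, 1.55 and 3.98, and gut and pancreas markers at 9.33, 8.82, 7.53 and 11.0.

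The bone-restricted genes summed to 968 ± 306 CPM in WT vehicle, 892 ± 580 in Runx2+/- vehicle, 15971 ± 3095 in WT MS-275 and 10193 ± 9808 in Runx2+/- MS-275. Genes of the fetal growth programme, such as Igf2 and H19, summed to 8666 ± 4685, 8466 ± 3727, 17617 ± 853 and 11141 ± 6275 CPM.

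Trunk tissue in the vehicle libraries could add skin, nerve and muscle. Summed trunk HOX genes averaged 2.05 times as much in WT vehicle as in WT MS-275 (13.6 ± 11.4 against 6.64 ± 0.767 CPM), but the ratio was 1.07 without WT vehicle replicate 3 and the lowest vehicle library held 0.805 times the highest MS-275 library. Replicates 1 and 2 of WT vehicle, with 8.22 and 6.00 CPM of these genes, held the neuronal list at 6.36 and 6.69 and the epidermal list at 6.34 and 5.11, which goes against trunk tissue, but a small share could lie hidden under the level in the MS-275 libraries.

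An older developmental age of the WT MS-275 libraries could raise bone genes. It would lower the fetal growth programme and embryonic globin, and neither was lower in WT MS-275. The former in WT vehicle was 0.492 times that in WT MS-275 and the embryonic share of beta-globin 0.758 times. But the former ranged widely within WT vehicle (5839, 6085 and 14074 CPM in replicates 1, 2 and 3). Since the groups also differ in tissue content, these markers cannot decide on age, which stays open.

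A few mitochondrial genes taking counts in the MS-275 libraries could shift the scaling. A shift would move the genes of a library alike, so under any scaling it could not part 2 lists. With library size only, the WT medians of the osteoblast (1.23, lower quartile 0.45) and epidermal list (−8.01, upper quartile −6.56) lay 9.24 apart. That gap restates the result rather than testing it anew, but a shift cannot be the whole cause of bone and skin genes moving apart. Removing these genes before TMM scaling, which trims such genes, left the osteoblast median at 1.98 and tests nothing. How much of the smaller medians a shift of scaling accounts for stays open.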
